A study of Mus musculus with 6 samples.

How the data were processed

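Gene expression was measured in epididymal white adipose tissue of 6 male mice with a one-colour (Cy3) Agilent mouse array, 1 array per animal. The 3 patDp/+ animals and the 3 wild type animals were assigned to their groups from the sample titles, which the description and genotype labels repeat. The source name of every sample carries the words wild type and replicate 1, so this field was not used for grouping, and the level of the duplicated genes served as a check of the groups. The series' design text speaks of separate mice, so the p-values of single genes measure the spread between animals.

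Per the file headers, each array was quantified with Feature Extraction 9.5.1.1, and the processed intensity values are background-subtracted and spatially detrended within an array, with a surrogate value for dim spots. They were not scaled between arrays. The mean and the local background intensity of each spot, as scanned and before subtraction, are also given per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.5 and limma 3.18.2 with no role for either. The authors also deposited a table of log2 values for the same 6 arrays whose columns share their quantiles. Which background correction preceded that table is not given in the sources used here. Its 6 columns were matched to the arrays by name, and each column correlated best with its own array (0.950 to 0.962, against 0.947 to 0.959 for the best other column). The median of each of its columns was 7.58 on the log2 scale. The table served as an alternative only.

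The main values were log2 of the processed intensity minus the 75th percentile of each array, over probes other than controls. Spots marked as outliers in the scanner files were left out and replicate spots of a probe were averaged. A probe was kept if it was marked well above background on at least 3 of the 6 arrays, which kept 27975 of 41174 probes. A gene was represented by its kept probe with the highest mean value, giving 19146 genes or unnamed features, of which 14525 had a current symbol. Names came from the scanner files, updated through the RefSeq accession of a probe where the gene table for assembly GRCm38.p6 held it (27050 probes matched). Coordinates are those of the probes on mm9, as the scanner files give them, and no coordinate of the gene table was used. Whether a probe lies in an exon or an untranslated region was not analysed here. For a gene not well above background on any array of 1 group, the fold is a lower bound, taken against the lowest signal among probes well above background on each such array, or the probe's own signal where higher.

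Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 6 arrays without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given with the log2 difference of a single gene are limma's standard errors. Those of a mean over genes, of a difference between such means and of the other probe of Pcsk6 were computed without limma. They come from the variance of the per-array values within each group. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 29 lists with at least 3 measured members. Camera sets the members of a list against all other genes, so at this preset its p does not measure the spread between animals. Each list was tested again with an estimated correlation, which allows for the members of a list varying together, and with fry, which tests whether the members of a list move one way on balance. Differences of single values were tested with exact permutation of the 6 arrays, where 3 against 3 cannot give a two-sided p below 0.1. Windows of 10 consecutive measured genes were ranked by their median difference. The lists, the tests, the main settings and the rule for naming genes were fixed before the data were examined. The rule names all measured genes of the interval list. Among genes with a symbol, it adds in each direction up to 12 past the adjusted threshold whose groups do not overlap, by largest difference. Where fewer than 5 qualify, the smallest unadjusted p completes them to 5. It also adds up to 4 members with the smallest p of each list described, and Lep, Adipoq, Pparg, Fasn, Ucp1, Adgre1, Ccl2 and Tnf. Ucp1 was not well above background on enough arrays to be tested. Some genes that the rule names are not reported here.

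Alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited table, other filters on dim probes, other ways of combining probes, slide or replicate blocks, array weights, another variance model, other thresholds, and leaving out each array in turn. Cyclic loess normalization and a narrower set of interval genes were added after the data were seen. The direction of a list under an alternative was read from its median and from the test. This rule replaced 1 based on the mean over members after results were seen, because the mean of the lipolysis list lay close to 0. The 6 arrays lay on 3 slides, and each slide held 1 wild type and 1 patDp/+ array with the same replicate number, so that slide and replicate number are 1 and the same block. Differences within each slide are therefore given for the gene lists.

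The share of probes well above background was 67.6%, 66.6% and 68.7% on the wild type arrays and 71.7%, 69.5% and 63.4% on the patDp/+ arrays, and at most 1 probe per array was saturated. The number of arrays limits the precision: the median standard error of a log2 difference was 0.12. The scripts were tested on simulated data made from the means and variances of the 19146 features for 3 patDp/+ against 3 wild type arrays, with 200 features changed and features varying independently. At an adjusted p under 0.05 the fit recovered 28.7% of features changed 1.5-fold, 78.1% of those changed 2-fold and 95.4% of those changed 4-fold. On average 8.95 unchanged features were called among 147.1 calls. A list shifted by 0.5 on the log2 scale was called by camera in all 20 simulated data sets. As features varied independently there, this does not test lists whose members vary together.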

Results

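Epididymal white adipose tissue, a visceral fat depot beside the testis, was profiled in 3 patDp/+ mice and 3 wild type mice, all male and 9 to 10 weeks old. patDp/+ mice carry an additional, paternally inherited copy of a stretch of chromosome 7 that matches the human region affected in 15q11-13 duplication syndrome. The stretch holds Herc2 at one end and Mkrn3 at the other. The series' title speaks of obesity with a late onset and of altered lipid metabolism, and the comparison asks which transcripts differ in the fat of young adults. All 6 arrays correlated with one another at 0.988 or more across genes, which are not independent replicates. The mean net signal of the negative controls was 36.7 on the array of patDp/+ replicate 1 and 29.0 to 31.6 on the other arrays.

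Genes of the duplicated interval were expressed at a higher level in patDp/+ fat. Of 16 genes on the interval list, 10 were measured, and 7 of these rose when adjusted over the list alone, while none passed over all genes tested. Snrpn, which encodes a small nuclear ribonucleoprotein, was 2.28-fold higher, with a mean log2 value of -0.58 ± 0.16 (SD, n = 3) in wild type and 0.60 ± 0.17 (SD, n = 3) in patDp/+ fat. Snurf, which shares its transcript with Snrpn and is thus no independent measurement, was 2.22-fold higher. Ndn, the gene of the growth suppressor necdin, was 2.12-fold higher, and Mkrn3, a ring finger gene, 1.87-fold. The log2 difference of Mkrn3 was 0.90, but 0.53 with the deposited table. Atp10a, a phospholipid-transporting ATPase gene, was 1.68-fold higher, Herc2, a ubiquitin ligase gene, 1.42-fold, and Ube3a, the ubiquitin ligase gene of Angelman syndrome, 1.41-fold (log2 difference 0.50 ± 0.07, SE). For these 7 genes every patDp/+ array lay above every wild type array, and each passed over the list alone under all alternatives in which genes were tested.

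The remaining 3 measured members did not pass. Peg12, whose probe lies just beyond that of Mkrn3, had a log2 difference of -0.24 ± 0.21 (SE), and the GABA receptor subunit genes Gabrg3 and Gabra5, which were near the detection limit, had -0.20 ± 0.45 and -0.58 ± 0.84. Without patDp/+ replicate 3, Gabrg3 passed as lower over the list alone (-0.69, adjusted p = 0.0425). Probes of Oca2, Magel2 and Ipw were well above background on fewer than 3 arrays and were not tested. The median log2 difference of the 10 members was 0.63 (fry adjusted p = 0.0484, exact permutation p = 0.1 for the mean over members, the smallest the design allows). The means over members within slides 1, 2 and 3 were 0.653, 0.245 and 0.62. The adjusted fry call was close to its threshold. It was lost with normexp and with quantile normalization (adjusted p = 0.0763 for each), with cyclic loess (0.0616), the deposited table (0.124), no filter on dim probes (0.0861) and the slide as a block (0.214), and without wild type replicate 2 (0.168), wild type replicate 3 (0.304), patDp/+ replicate 1 (0.22), patDp/+ replicate 2 (0.32) or patDp/+ replicate 3 (0.0657). The camera call (adjusted p = 6.5e-10) was lost with an estimated correlation (adjusted p = 0.28).

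**Figure D1:**
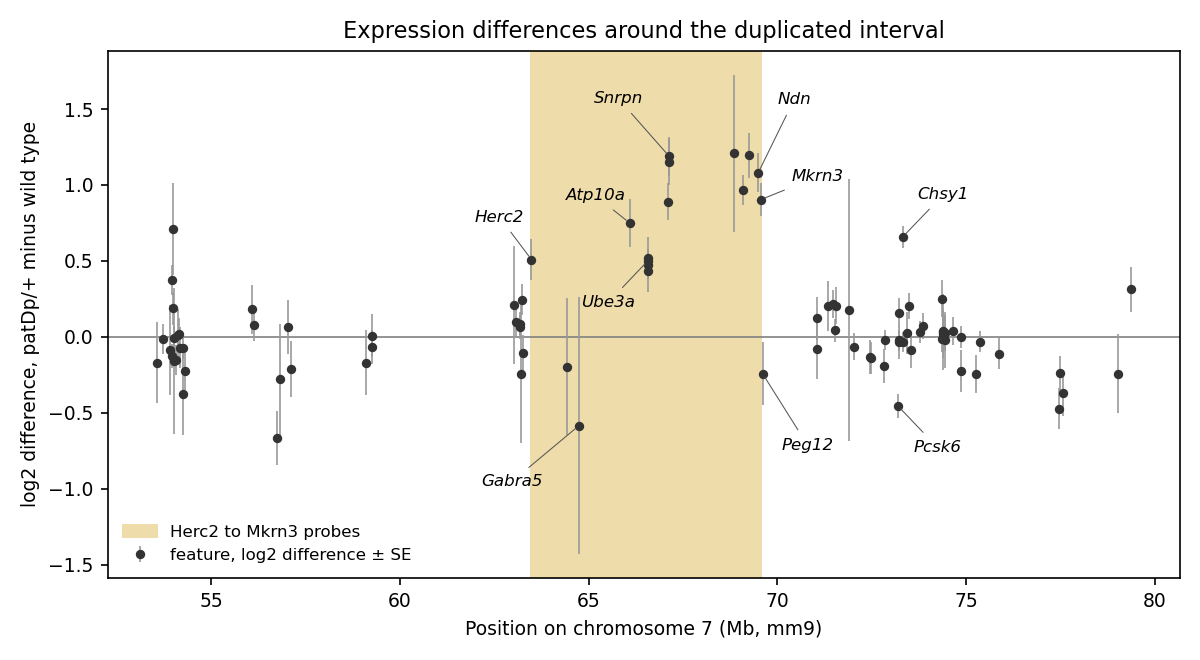
Log2 difference (patDp/+ minus wild type) of each measured feature against its probe position on chromosome 7 in Mb (mm9), with bars giving limma's SE, and the stretch between the Herc2 and Mkrn3 probes shaded. Of the 16 features in the shaded stretch, 13 were higher at an unadjusted p under 0.05, and features on both sides scatter around 0.

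Features were also taken by position alone. Between the Herc2 probe (chromosome 7, start 63485047, mm9) and the Mkrn3 probe (end 69562792, mm9), a distance of 6.08 Mb, 16 features were measured, named or not. Of these, 13 were higher in patDp/+ fat when adjusted over the interval alone and 0 were lower, against 2.68% of all features that were higher at an unadjusted p under 0.05. Their median log2 difference was 0.82, or 0.73 with the 1 feature below background in wild type set to its lower bound. Among 18734 windows of 10 consecutive genes, the first rank was shared by windows that start between the Ube3a and Snrpn probes, with a median of 1.02. The highest window that did not touch the interval, on chromosome 11, had a median of 0.50. Next to the interval, the list of flanking genes had a median of 0.10 over 13 measured members with 0 at an unadjusted p under 0.05. Nipa1 (0.25 ± 0.10, SE), Mtmr10 (0.22 ± 0.09), Mcee (0.20 ± 0.12) and Tjp1 (-0.13 ± 0.11) had the smallest p among them, and the list was not called (camera adjusted p = 0.0831), except with array weights (0.0332) and without wild type replicate 2 (0.0359).

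**Figure D2:**
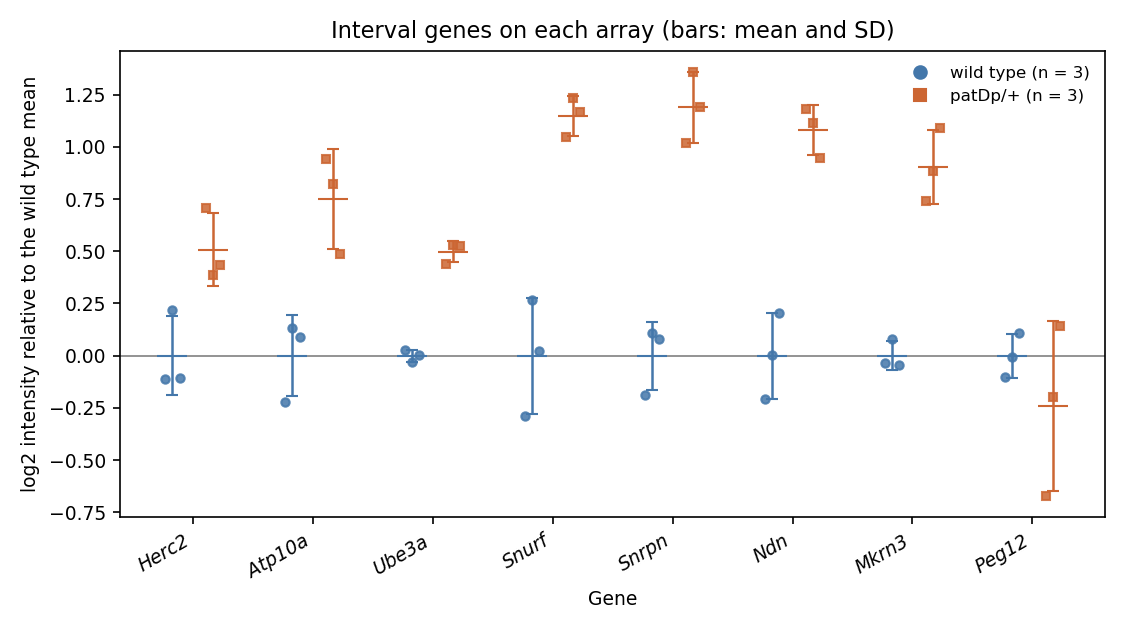
Log2 intensity of 8 interval genes on each of the 6 arrays, relative to the wild type mean of the gene, with horizontal marks for the group mean and bars for the SD (n = 3). The patDp/+ points lie above all wild type points for 7 genes, and for Peg12 the groups overlap.

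Beyond the interval, no single gene passed over all 19146 tested: 0 genes reached an adjusted p under 0.05 in limma, where the smallest was 0.345. At an unadjusted p under 0.05 there were 1074 genes, 514 higher and 560 lower, where chance alone gives 957.3 on average. The groups did not overlap for 11.2% of genes, against 10% by chance. With the smallest p of all, Cd8a, the alpha chain of the CD8 co-receptor of cytotoxic T cells, had a log2 difference of 1.35 ± 0.13 (SE). A330076H08Rik, a transcript inside the duplicated interval, had 0.97 ± 0.10, and Chsy1, a chondroitin synthase gene on chromosome 7, 0.66 ± 0.07. Snrpn and Ndn completed the 5 leading higher genes. Features of the immunoglobulin kappa locus without a symbol led the lower side, with a difference of -1.23 ± 0.15 for the smallest p among them. The leading lower genes with a symbol were Pdgfrl (-0.51 ± 0.07), Pgbd5 (-0.75 ± 0.12), Mmd2 (-2.67 ± 0.46), the proprotein convertase gene Pcsk6 (-0.46 ± 0.08) and Sfrp1, a secreted Wnt inhibitor (-0.69 ± 0.12). The sign of Pgbd5 turned with normexp background correction (0.32), and the values of these genes outside the interval did not pass the adjusted threshold. The count of 1074 depended on single arrays. It was 764 without patDp/+ replicate 1 and 755 without patDp/+ replicate 2, but 1779 without patDp/+ replicate 3. Array weights gave 1740. With the slide as a block the counts were 0 and 980.

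Among the gene lists, those of T and NK cells and of B cells moved in opposite directions. The T and NK cell list was shifted upward with a median log2 difference of 0.34, and 15 of 18 measured members were higher. Cd8a and Cd8b1, the genes of both CD8 chains, rose when adjusted over the list alone (1.35 ± 0.13 and 1.18 ± 0.16, SE), also when any 1 array was left out. The Cd8a probe lies on chromosome 6, beyond the immunoglobulin kappa locus whose features led the lower side. Whether these differences are linked was not tested. The difference of Cd8a was 0.51 with the deposited table. The T cell receptor complex gene Cd3d was higher by 0.45 ± 0.13 and Cd6 by 0.46 ± 0.14 without passing, although Cd3d passed over the list alone with the slide as a block (0.0431), with array weights (0.044) and without wild type replicate 1 (0.0381), and both did without patDp/+ replicate 2 (0.034 for each). The mean over the list was higher within each slide (0.306, 0.244 and 0.417), and the camera adjusted p was 4.85e-06, with an adjusted p = 0.384 with an estimated correlation. The median was 0.18 with the deposited table and 0.18 without wild type replicate 3, where the list stayed called (0.00367). The B cell list was shifted downward with a median of -0.52, and 11 of 12 members were lower. Fcmr, an IgM receptor, had -1.04 ± 0.35, Cxcr5, the receptor that guides B cells into follicles, -0.69 ± 0.25, Cd79b, part of the B cell receptor, -0.74 ± 0.28, and Fcer2a -0.44 ± 0.18. The within-slide means of the B cell list were -0.795, -0.427 and -0.299. Its camera adjusted p was 7.49e-05, and its adjusted p = 0.384 with an estimated correlation. The direction of the B cell list depended on the background correction, as its median was 0.17 with normexp (camera adjusted p = 0.759), and it was -0.24 with the deposited table. None of its members passed over the list alone, but Fcmr, Cxcr5, Cd79b and Fcer2a did with the slide as a block (0.0357 for each), with array weights (0.0187 for each) and without patDp/+ replicate 3 (0.00428 for Fcmr and Cxcr5, 0.00504 for Cd79b and 0.0115 for Fcer2a). The signs of Cxcr5 (0.32) and Fcer2a (0.39) turned with normexp.

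The lists of inflammation and of the extracellular matrix had positive medians, with the shift mainly on 2 of the 3 slides. Their camera calls were lost with an estimated correlation. The list of inflammatory cytokines and acute phase genes had a median log2 difference of 0.48, with 18 of 20 measured members higher and 7 at an unadjusted p under 0.05, but 0 when adjusted over the list alone. The monocyte chemokine genes Ccl7 and Ccl2 were higher by 1.08 ± 0.28 and 1.01 ± 0.38 (SE), the acute phase gene Saa3 by 0.37 ± 0.10, the adhesion molecule gene Icam1 by 0.24 ± 0.07 and the cytokine signalling inhibitor Socs3 by 0.62 ± 0.19. Tnf had 0.43 ± 0.33. The macrophage list had a median of 0.24, with 26 of 28 members higher and 1 at an unadjusted p under 0.05. Its leading members were Timd4 (0.19 ± 0.07), Msr1 (0.32 ± 0.14), Itgam (0.43 ± 0.19) and C1qc (0.27 ± 0.12), and the macrophage marker Adgre1 had 0.17 ± 0.10. In the list of fibroblasts and extracellular matrix, with a median of 0.17 and 21 of 26 members higher, Thbs1 (0.93 ± 0.25), Ccn2 (0.79 ± 0.22), Timp1 (0.76 ± 0.25) and the collagen gene Col5a1 (0.27 ± 0.09) led. Egr2 (0.77 ± 0.22), Junb (0.31 ± 0.16), Atf3 (0.48 ± 0.27) and Fosb (0.67 ± 0.42) led the list of immediate early and heat shock genes, with a median of 0.15.

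Camera called all 4 of these lists higher, with adjusted p of 1.34e-06 for cytokines, 1.55e-06 for macrophages, 4.83e-06 for extracellular matrix and 0.0275 for immediate early genes. The exact permutation p for the mean over members was 0.1 for cytokines and matrix, 0.4 for macrophages and 0.3 for immediate early genes. With an estimated correlation the calls were lost, with an adjusted p = 0.384 for the first 3 lists and an adjusted p = 0.56 for the last. For the first 3 lists the shift was carried by slides 1 and 2: within slides 1, 2 and 3 the means were 0.745, 0.573 and 0.0736 for the cytokine list, 0.611, 0.38 and -0.274 for the macrophage list, and 0.362, 0.317 and 0.0391 for the matrix list. The immediate early list had 0.433, -0.0776 and 0.0988, so that slide 1 carried most of its shift. Ccl2 differed by 1.56, 1.68 and -0.22 within the same slides. Without patDp/+ replicate 1 the medians were 0.32 for cytokines, 0.11 for macrophages and 0.10 for matrix, with the calls kept, and without patDp/+ replicate 3 the medians were 0.37 for macrophages and 0.23 for immediate early genes. Without that array 4 cytokine, 7 macrophage and 2 matrix members passed as higher over their list alone, as did 1 cytokine member without patDp/+ replicate 2 and 1 matrix member each without patDp/+ replicate 1 and without wild type replicate 3. An immediate early member did so without wild type replicate 2 (0.0116). Array weights gave 3 such cytokine members and the other variance model 4. With normexp the calls of the macrophage (adjusted p = 0.148, median 0.15), matrix (0.759, median 0.08) and immediate early (0.827, median 0.07) lists were lost, and with the deposited table the cytokine median was 0.30. The immediate early call was also lost with no filter on dim probes (adjusted p = 0.0958) and without wild type replicate 1 (0.223, median 0.07), wild type replicate 3 (0.31), patDp/+ replicate 1 (0.0958, median 0.09) or patDp/+ replicate 2 (0.166, median 0.06).

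The list of markers of fat expansion was called higher by camera, with 7 of 11 members higher and a median log2 difference of 0.13 (adjusted p = 0.0156, but 0.384 with an estimated correlation). Sfrp5, a secreted Wnt inhibitor of adipocytes, passed when adjusted over the list alone (0.0484), with a difference of 1.78 ± 0.41 (SE) or 3.43-fold. That single call was lost with the slide as a block (0.131), with no filter on dim probes (0.0782) and without wild type replicate 1 (0.194), wild type replicate 2 (0.177), patDp/+ replicate 1 (0.105) or patDp/+ replicate 2 (0.0568). With the deposited table the difference of Sfrp5 was 0.81. Bmp3 (0.99 ± 0.34), the natriuretic peptide clearance receptor gene Npr3 (0.58 ± 0.19) and the leptin gene Lep (0.45 ± 0.19) did not pass, although Lep did without patDp/+ replicate 3 (0.65, adjusted over the list alone 0.0183), as did Bmp3 and Npr3 without wild type replicate 3 (0.0203 and 0.016) and with the other variance model (0.0488 for each), and all 3 with the deposited table (0.0327 to 0.044). Within slides 1, 2 and 3 the list's means were 0.542, 0.735 and -0.132, and Lep differed by 0.89, 0.42 and 0.03. The camera call of the list was also lost with normexp (adjusted p = 0.814, median 0.0008), without patDp/+ replicate 1 (0.119) and without wild type replicate 2 (0.0931, median 0.04), and the median was 0.26 without wild type replicate 1 and 0.35 without patDp/+ replicate 3.

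**Figure D3:**
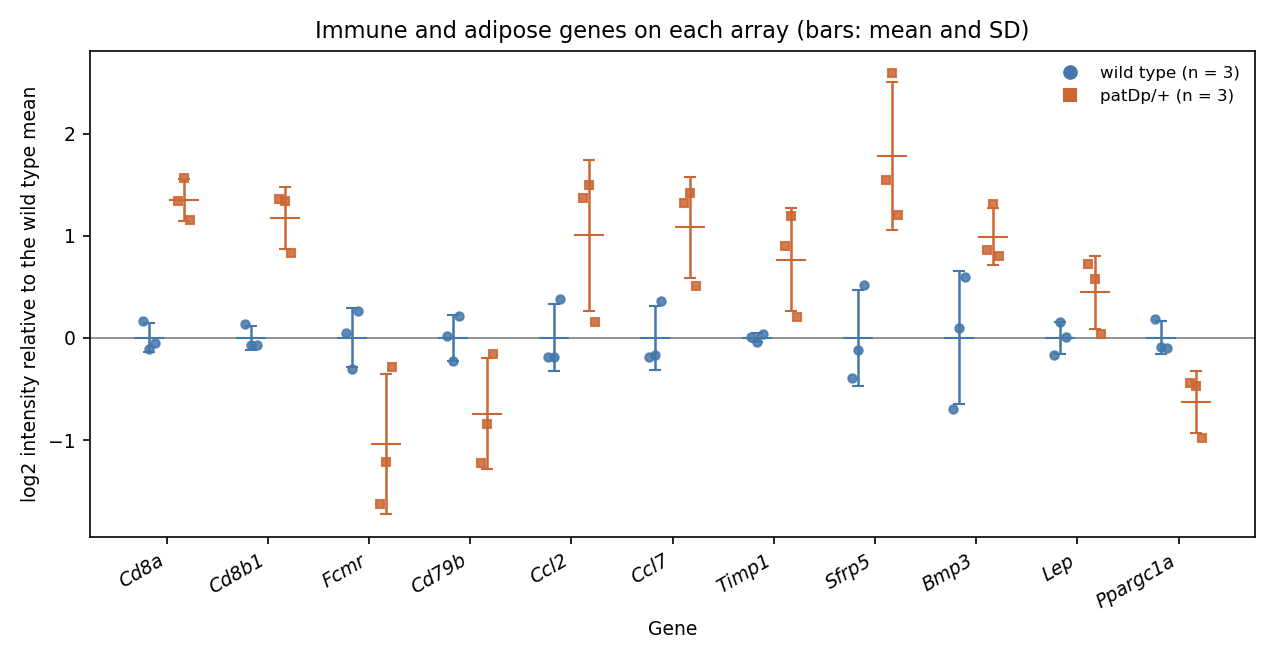
Log2 intensity of 11 named immune and adipose genes on each array, relative to the wild type mean of the gene, with marks for the group mean and bars for the SD (n = 3). For Cd8a and Cd8b1 all patDp/+ points lie well above the wild type points, while for Ccl2 and Lep 1 patDp/+ point, that of replicate 3, lies within the wild type range.

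The lists of lipid synthesis and of mitochondrial metabolism had slightly negative medians. Their camera calls were lost with an estimated correlation. The mean over the synthesis list differed in sign between slides (exact permutation p = 0.5). The list of fatty acid and triglyceride synthesis had a median log2 difference of -0.18, with 20 of 25 members lower, led by the phosphatidate phosphatase gene Lpin1 (-0.40 ± 0.12, SE), Mogat1 (-0.40 ± 0.14), the carbohydrate-responsive transcription factor gene Mlxipl (-0.38 ± 0.15) and the desaturase gene Fads1 (-0.26 ± 0.11). Of these, only Lpin1 passed over the list alone under an alternative, with the deposited table (-0.44, adjusted p = 0.0488). Fasn, the fatty acid synthase gene, had -0.01 ± 0.28. In the list of oxidative phosphorylation, 21 of 23 members were lower with a median of -0.12, and Sdha (-0.19 ± 0.09), Uqcrc2 (-0.19 ± 0.11) and Atp5c1 (-0.17 ± 0.10) were among those with the smallest p. The list of fatty acid oxidation had a median of -0.12, with 20 of 24 members lower. Acot2 (-0.24 ± 0.11), the lipid-sensing receptor gene Ppara (-0.29 ± 0.13) and Eci1 (-0.23 ± 0.11) were lower, whereas Cpt1a, which controls the entry of fatty acids into mitochondria, was higher by 0.23 ± 0.09. Ppargc1a, a coactivator of mitochondrial biogenesis, had the smallest p in the list of brown and beige fat (-0.63 ± 0.17), followed by Ebf2 (-0.12 ± 0.07), Pank1 (-0.29 ± 0.19) and Prdm16 (-0.22 ± 0.16). The median of that list was -0.15, with 10 of 13 members lower. Lpin1 with the deposited table apart, no member of these 4 lists passed over its list alone.

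The list of lipolysis and lipid droplets had a median of -0.11, with 16 of 20 members lower, among them the seipin gene Bscl2 (-0.26 ± 0.10, SE), Gyk (-0.33 ± 0.17), Abhd5 (-0.32 ± 0.17) and Pde3b (-0.25 ± 0.14). Its mean was 0.01, of the opposite sign to its median and its test. Adrb1 (2.17 ± 1.62), the member with the largest difference, pulled that mean upward. The mean was -0.08 with the filter on all 6 arrays. Camera called these 5 lists lower, with adjusted p of 0.000763 for synthesis, 0.000561 for oxidative phosphorylation, 0.0141 for oxidation, 0.0388 for brown and beige fat and 0.0387 for lipolysis. None held with an estimated correlation, with an adjusted p = 0.56 for synthesis, oxidative phosphorylation and oxidation, an adjusted p = 0.384 for brown and beige fat and an adjusted p = 0.526 for lipolysis. The exact permutation p for the mean over members was at least 0.3 for each of the 5 lists. Slide 2 carried most of the shift, with means of -0.854 for synthesis, -0.282 for oxidative phosphorylation, -0.243 for oxidation and -0.461 for brown and beige fat. On slide 1 these were 0.164, -0.0361, -0.0639 and -0.122, and on slide 3 they were 0.0969, -0.0181, 0.0111 and 0.0488. The lipolysis list had -0.22, 0.141 and 0.0963 on slides 1, 2 and 3.

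Single arrays decided most of these lipid and mitochondrial calls. Without patDp/+ replicate 2 the adjusted p was 0.139 for fatty acid and triglyceride synthesis, 0.208 for oxidative phosphorylation, 0.129 for fatty acid oxidation, 0.142 for brown and beige fat and 0.127 for lipolysis. Without wild type replicate 2 it was 0.235 for synthesis, 0.181 for oxidation, 0.505 for brown and beige fat and 0.0795 for lipolysis. Without patDp/+ replicate 1 it was 0.355 for oxidation, 0.281 for brown and beige fat and 0.247 for lipolysis. Without wild type replicate 3 it was 0.0776 for oxidation and 0.0566 for brown and beige fat, and without wild type replicate 1 it was 0.367 for lipolysis. The medians shrank to -0.07 for synthesis, -0.04 for oxidative phosphorylation, -0.05 for oxidation and -0.09 for brown and beige fat without patDp/+ replicate 2, to -0.05 for synthesis and -0.07 for oxidation without wild type replicate 2, and to -0.07 for oxidation and -0.05 for lipolysis without patDp/+ replicate 1. Conversely, they were larger in size without patDp/+ replicate 3, at -0.37 for synthesis, -0.19 for oxidative phosphorylation, -0.19 for oxidation and -0.30 for brown and beige fat, and without wild type replicate 1, at -0.41 for synthesis and -0.25 for brown and beige fat. With normexp they were -0.33 for synthesis, -0.24 for oxidative phosphorylation, -0.20 for oxidation and -0.22 for lipolysis, and with array weights -0.35 for synthesis and -0.18 for oxidative phosphorylation. The lipolysis call was also lost with the slide as a block (adjusted p = 0.0687), with array weights (0.0605), with quantile normalization (0.118), with the deposited table (0.0948), with the mean over probes (0.114) and with the filter on all 6 arrays (0.0557). The brown and beige call was lost with quantile normalization (0.0632), cyclic loess (0.0517) and no filter (0.0571), and its median turned to 0.08 with normexp (0.363).

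The identity genes of adipocytes were not called (camera adjusted p = 0.0912), with a median log2 difference of -0.10 over 24 members. Adipoq, the adiponectin gene, had -0.08 ± 0.07 (SE), and Pparg, the master regulator of adipocyte formation, 0.06 ± 0.11. Trarg1 (-0.17 ± 0.09), Retn (-0.18 ± 0.09) and Acsl1 (-0.36 ± 0.19) had small negative differences. This list was called lower with normexp (adjusted p = 2.02e-07) and with no filter (0.0257). The list of insulin signalling and glucose use had a median of -0.11 and was not called (0.224), except with normexp (2e-04). Its leading members were the glycogen synthase gene Gys1 (-0.26 ± 0.08), Grb14 (0.74 ± 0.32), Ptpn1 (0.19 ± 0.09) and Tbc1d4 (-0.21 ± 0.11). In the list of cholesterol synthesis, with a median of -0.11 and an adjusted p of 0.535, no member passed over the list alone. Sqle had -0.39 ± 0.18 and Cyp51 -0.45 ± 0.21, and Fdft1 had -0.24 ± 0.08 by its brightest probe but 0.01 with the mean of its probes. The cholesterol list was called without patDp/+ replicate 1 (adjusted p = 0.0432).

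Endothelial genes were lower by a small amount. Their list had a median log2 difference of -0.16, with 18 of 20 members lower, led by the transcription factor genes Sox17 (-0.40 ± 0.12, SE) and Sox18 (-0.31 ± 0.11), Emcn (-0.21 ± 0.08) and Egfl7 (-0.25 ± 0.10). None passed as lower over the list alone, and 1 other member passed as higher without patDp/+ replicate 3 (0.00572). The camera adjusted p was 0.00206, with an adjusted p = 0.384 with an estimated correlation. Within slides the means were -0.23, -0.0765 and -0.0758, and the call was lost without wild type replicate 1 (adjusted p = 0.08, median -0.07) and without patDp/+ replicate 1 (0.0553). The interferon response list was also shifted downward, with a median of -0.16 and 17 of 20 members lower, among them the antiviral genes Ifit2 (-0.32 ± 0.12), Mx2 (-0.29 ± 0.12) and Ifit1 (-0.34 ± 0.15) and the regulator Irf7 (-0.20 ± 0.09). Its camera adjusted p was 0.000536, with an adjusted p = 0.526 with an estimated correlation. The within-slide means were -0.22, -0.187 and -0.0129, and the call was lost with array weights (adjusted p = 0.14, median -0.09) and without wild type replicate 1 (0.08, median -0.09).

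Markers of other cells that fat samples can hold were not called. Smooth muscle and pericyte genes had a median of -0.11 and a mean of 0.02, of opposite signs, and Synpo2 (0.94 ± 0.29, SE), Actg2 (0.24 ± 0.11), Rgs5 (-0.17 ± 0.09) and Acta2 (0.38 ± 0.26) led. Synpo2 and Acta2 passed over the list alone without wild type replicate 3 (0.0335 and 0.0279). Mesothelial genes, which line the depot, had a median of 0.07, with Msln (0.31 ± 0.16), Muc16 (0.29 ± 0.22), Gpm6a (0.20 ± 0.17) and Upk3b (0.16 ± 0.15). They were called higher without patDp/+ replicate 1 (adjusted p = 0.00415) and without wild type replicate 3 (0.00134). Epididymis and testis genes had a median of -0.07 over 9 members, with Rnase10 (-0.59 ± 0.28), Prm1 (-0.56 ± 0.43), Tnp1 (-0.14 ± 0.11) and Lcn9 (-0.09 ± 0.12). With normexp their median was 0.54 and they were called higher (0.0354). Skeletal muscle genes had a median of 0.02, although Acta1, the skeletal actin gene, passed when adjusted over the list alone (1.30 ± 0.27, adjusted p = 0.0326). That call was lost with no filter (0.0702) and without wild type replicate 1 (0.0716), wild type replicate 2 (0.0875) or patDp/+ replicate 1 (0.0664). Myh2 (0.61 ± 0.23), Tnnc2 (0.42 ± 0.25) and Actn3 (-0.51 ± 0.31) did not pass, except Myh2 without wild type replicate 3 (0.0455). The muscle list was called higher with normexp (0.0151) and with no filter (0.0369). Red blood cell genes had within-slide means of -0.314, -0.42 and 1.32. On slide 3 the macrophage list had -0.274 and the cytokine list 0.0736. Both arrays of that slide made up the value of 1.32. Relative to the mean over arrays, the red blood cell list was highest on patDp/+ replicate 3 (0.823) and lowest on wild type replicate 3 (-0.497). Ahsp (0.38 ± 0.52), Slc4a1 (0.28 ± 0.46) and the alpha globin genes Hba-a1 (0.16 ± 0.27) and Hba-a2 (0.13 ± 0.25) led that list, which was called without patDp/+ replicate 1 (0.0113).

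**Figure D4:**
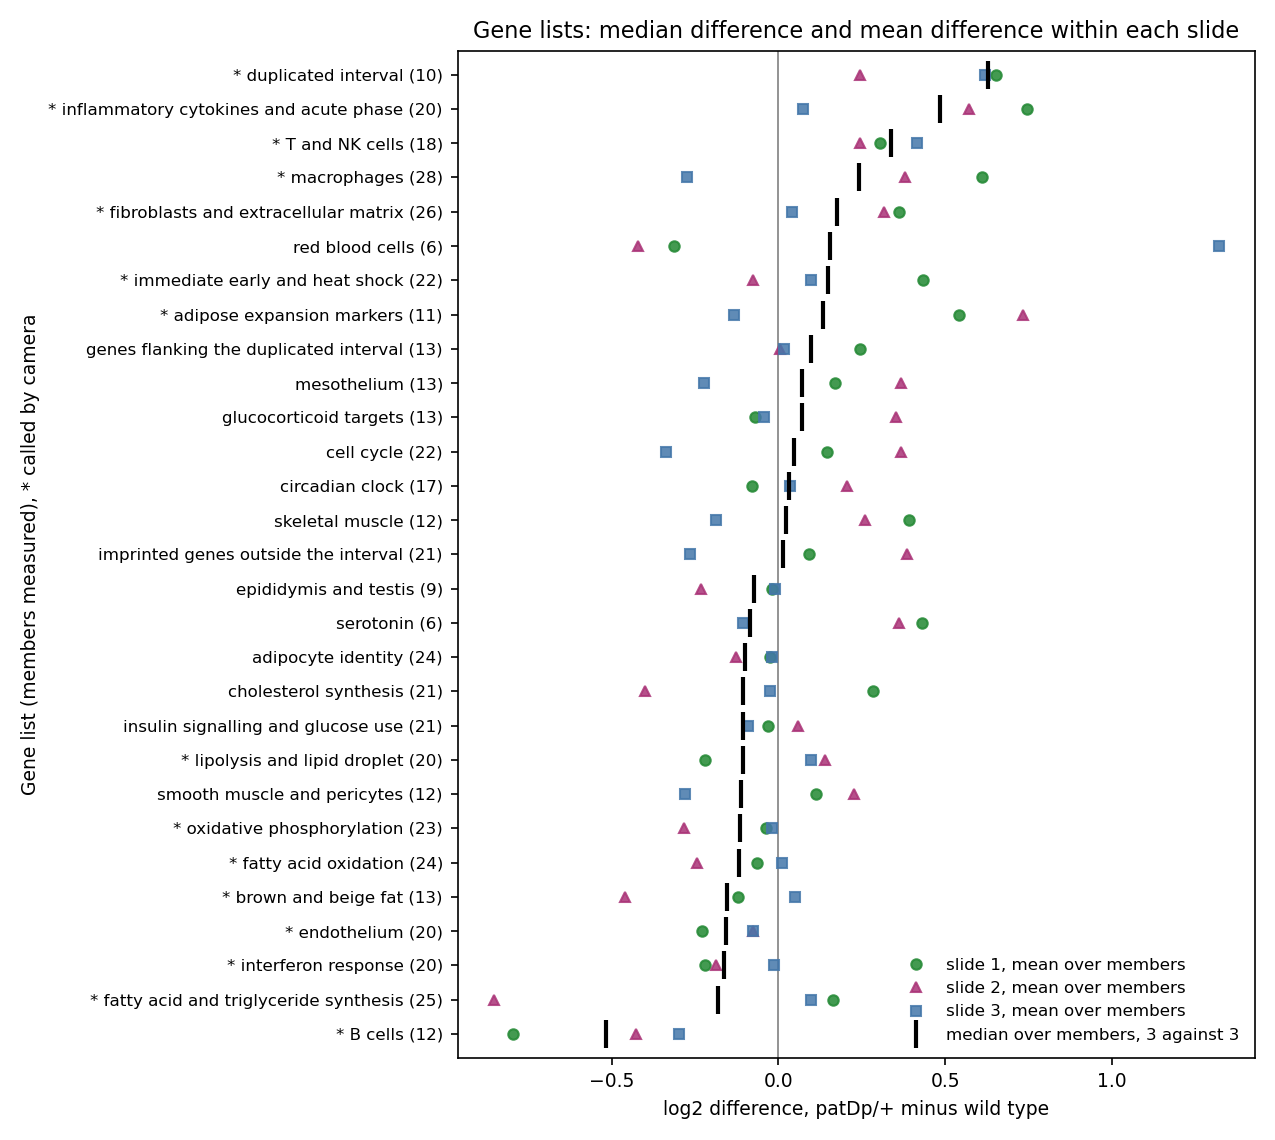
Median log2 difference (patDp/+ minus wild type) over the measured members of each of the 29 gene lists (black marks) and the mean over members within each of the 3 slides, each slide comparing 1 patDp/+ with 1 wild type array. Stars mark the 15 lists called by camera with its preset correlation, none of which was called with an estimated correlation. The T and NK cell and B cell lists have 1 sign on all 3 slides. So do other lists, such as the interval, cytokine, matrix, endothelium, interferon and oxidative phosphorylation lists and the uncalled adipocyte identity list. The median of the B cell list turns to 0.17 with normexp.

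The remaining lists were not called. Imprinted genes outside the interval had a median log2 difference of 0.01. Within that list no member passed over the list alone. Rian, a maternally expressed noncoding RNA, had 0.81 ± 0.28 (SE), H19 -0.36 ± 0.18, Airn -0.24 ± 0.12 and Slc38a4 -0.31 ± 0.10 (0.63 with normexp). In the circadian clock list, with a median of 0.03, Bhlhe40 (0.67 ± 0.17) and Bhlhe41 (0.30 ± 0.11), a pair of related repressors, were higher on all 3 slides without passing over the list alone, although Bhlhe40 passed with the slide as a block (0.042), and Nfil3 (0.29 ± 0.16) and Tef (-0.27 ± 0.12) followed. Glucocorticoid targets had a median of 0.07, with Cdkn1a (0.44 ± 0.15, passing over the list alone only without patDp/+ replicate 3, at 0.0284), Mt2 (0.43 ± 0.31), Ddit4 (-0.22 ± 0.15) and Sgk1 (-0.17 ± 0.14), and were called higher with array weights (adjusted p = 0.0447) and without wild type replicate 1 (0.0287). Cell cycle genes had a median of 0.05, with Ccnb1 (0.43 ± 0.20), Aurka (0.14 ± 0.08), Ube2c (0.24 ± 0.14) and Aurkb (0.27 ± 0.22), and were called higher without patDp/+ replicate 3 (adjusted p = 0.000302) without wild type replicate 3 (0.0262), with array weights (0.0398) and with normexp (0.0418). Of the serotonin list, with a median of -0.09 over 6 members, the receptor gene Htr7 was well above background on 0 wild type and 3 patDp/+ arrays and was at least 1.9-fold higher (adjusted p = 0.87). Adjusted over the list alone it missed the threshold (0.0693), and passed with the slide as a block (0.00204), without wild type replicate 3 (0.0418) and without patDp/+ replicate 2 (0.0393). Maob (-0.24 ± 0.12), Maoa (0.10 ± 0.14) and the serotonin transporter gene Slc6a4 (-0.21 ± 0.15) did not pass either, and the mean of the list, 0.23, had the opposite sign to its median.

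Of 29 lists, camera thus called 15, of which 7 were higher and 8 lower. With an estimated correlation 0 lists were called, and fry called 1, that of the duplicated interval, by direction, a call lost under most alternatives. Testing for change in either direction, fry called 2, the interval list and the T and NK cell list (adjusted p = 0.00147 for each). With the slide as a block camera called 14 lists.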

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

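The values with cyclic loess and for the narrower set of interval genes were chosen after the data were seen, and the other alternatives before. The duplicated interval kept its direction under every alternative run, and its fry p unadjusted for the other lists stayed under 0.05. Adjusted over the 29 lists, where it was 0.0484, it stayed under 0.05 in 5 of 16 alternatives and rose to as much as 0.32. Its median log2 difference was 0.50 to 0.83 over the processing alternatives, 0.90 for the 7 members between Herc2 and Mkrn3 well above background on all 6 arrays, and 0.58 to 0.72 when 1 array was left out. The set of 7 leaves out every measured member that did not rise, so its higher median follows from that choice. Windows of the interval kept the first rank except with no filter on dim probes, where the best rank was 3 (the cause was not tested). It was 1 to 1 when 1 array was left out. With limma, 0 genes passed the adjusted threshold under every alternative (0 to 0 when 1 array was left out), while 104 had an unadjusted p under 0.01 and at least 1.5-fold, a looser threshold. The 1074 genes at an unadjusted p became 1740 with array weights and 755 to 1779 when 1 array was left out, the highest without patDp/+ replicate 3 (cause not tested). Of them 47.9% were higher, against 63.8% with normexp, 60.7% with no filter, 37.8% without patDp/+ replicate 1, 40.6% without wild type replicate 2 and 61.4% without patDp/+ replicate 3. The 15 lists called became 0 with an estimated correlation, which allows for members that vary together, 1 with fry, which asks another question, and 9 to 16 when 1 array was left out, the lowest without patDp/+ replicate 2. The lists of cytokines and of T and NK cells were called under all 16 processing alternatives and omissions. Same-numbered arrays, which also shared a slide, had deviations that correlated at 0.106, -0.0898 and -0.039. These values show no strong shared deviation, but cannot tell whether same-numbered animals were matched. The replicate block gave 0 genes past the threshold, 980 at an unadjusted p, a median of 0.63 for the interval and 14 lists, and ended the camera call of lipolysis, the adjusted fry call of the interval (0.214) and, over its list alone, the call of Sfrp5. With normexp, which handles dim probes differently, the sign turned for the lists of epididymis and testis (0.54), B cells (0.17) and brown and beige fat (0.077), and for Pgbd5 (0.32), Cxcr5 (0.32), Fcer2a (0.39) and Slc38a4 (0.63), and with the mean of probes for Fdft1 (0.011), where the cause was not tested. These 3 list results are counted by median and test, a rule set after results were seen. By the mean over members, the earlier rule, 10 results in 4 lists turned, 6 of them of the lipolysis list, whose mean was 0.01. Signal over background limits genes such as Gabra5 and Htr7, which were well above background on only part of the arrays.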

Other observations

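Tests of explanations in this part were chosen after the results were seen, as were the immunoglobulin and chemokine features. The lowest windows of the genome lay in immunoglobulin light chain loci, taken here as all measured features between the named genes on either side. All 6 measured features of the lambda locus on chromosome 16, between Hira and Olfr166, were lower in patDp/+ fat, with log2 differences from -2.23 to -1.13, and 5 had an unadjusted p under 0.05. Their mean was -1.625 ± 0.372 (SE, exact permutation p = 0.1, the smallest possible), within slides -2.48, -1.36 and -1.03, and -1.07 ± 0.369 with normexp. The 40 features of the kappa locus on chromosome 6, between Serbp1 and Rpia, went both ways, with 22 lower, 8 of them at an unadjusted p under 0.05, and 18 higher, 2 of them so. Their mean was -0.25 ± 0.085, and 0.35 ± 0.4 with normexp, although the lowest windows, with a median of -1.28, lay within this locus. The probe of Cd8a, the leading higher gene, lies on the same chromosome (start 71327330, mm9), beyond the last measured kappa feature (end 70653980). Whether these differences arise from this stretch of chromosome 6 or from T and B cells was not tested. The 40 features of the heavy chain locus on chromosome 12, between Tmem121 and Zfp386, went both ways, 13 higher and 27 lower, with a mean of 0.08 ± 0.103, and 0.53 ± 0.378 with normexp. Related segments of these loci can share probe signal, so the features are not independent.

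The highest windows outside the interval held chemokine genes of chromosome 11. All 10 measured Ccl genes of that chromosome were higher over the 3 against 3 arrays, with a median of 0.50, and 4 had an unadjusted p under 0.05. Ccl5 (0.54 ± 0.19, SE) and Ccl4 (0.76 ± 0.27) were higher on all 3 slides, by 0.48, 0.41 and 0.73 and by 1.23, 0.12 and 0.93, as were Ccl7, Ccl11 and Ccl3. On slide 3, Ccl2, Ccl8, Ccl9 and Ccl6 were lower (-0.22, -1.07, -0.34 and -0.37), as was Ccl12 on slide 1 (-0.295).

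An extra paternal copy takes genes active only from the paternal chromosome from 1 to 2 active copies, a predicted log2 difference of 1, and other genes from 2 to 3, a predicted difference of 0.585. Between the Herc2 and Mkrn3 probes the members known as paternally expressed, Snrpn (for Snurf as well), Ndn and Mkrn3, had a mean of 1.06 ± 0.08 (SE), and the 5 others, Herc2, Atp10a, Ube3a, Gabrg3 and Gabra5, one of 0.20 ± 0.30. The sets differed by 0.86 ± 0.27 (0.644, 1.35 and 0.592 within slides, exact permutation p = 0.1). With Peg12, also paternally expressed but with its probe beyond that of Mkrn3, the first mean fell to 0.73 ± 0.11 and the difference to 0.54 ± 0.26. Gabrg3 and Gabra5, near the detection limit, carried much of this: without them, which also leaves out the others that did not rise, the 3 others had a mean of 0.59 ± 0.09 and the sets differed by 0.47 ± 0.105, or by 0.15 ± 0.15 with Peg12. For the members between the Herc2 and Mkrn3 probes, a trend of signal with intensity between arrays was argued against as the whole cause, since the difference was 0.88 ± 0.26 after cyclic loess, or 0.47 ± 0.11 without those 2 genes. Whether the dose of active alleles sets the sizes stays open, as the difference depends on which members are counted and whether Peg12 lies in the duplicated stretch was not tested. Nor was the imprinting of Atp10a and Ube3a in fat.

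A second pattern is the rise of the macrophage, T cell and matrix lists beside lower B cell and lipid lists. If a lower share of adipocytes raised all other cell types alike, endothelial genes would rise too. Their list was below 0 (-0.13 ± 0.04, SE, exact permutation p = 0.1). The mean of the 3 raised lists exceeded the endothelium list by 0.39 ± 0.12 (exact permutation p = 0.1). Those lists were picked because they rose, so this difference cannot decide the question. Lymph node tissue in some samples would move T and B cells together. T minus B was 0.83 ± 0.28 (exact permutation p = 0.1), or 0.42 ± 0.19 with normexp. As the pattern was itself a rise of the T cell list and a fall of the B cell list, this difference restates it and cannot decide the question. For the B cell list alone the handling of the background of dim probes stays open, as its mean went from -0.51 ± 0.22 to 0.057 ± 0.375 with normexp. A change within immune cells, their number or the genotype itself may also underlie the pattern and was not tested.

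Chsy1 and Pcsk6, among the 5 leading genes with a symbol in each direction, have their probes 3.76 and 3.63 Mb beyond the Mkrn3 probe. Other sequence next to the interval, carried along with the modified chromosome, is a candidate explanation. Of the 72 other genes within 10 Mb of the interval, 4 (5.56%) had an unadjusted p under 0.05, against 5.56% elsewhere (Fisher's exact p = 1, two-sided). This shows no excess among the neighbours and leaves open a difference that touches only a few genes. Whether a base difference under a probe lowered Pcsk6 stays open. Its other probe was lower as well (-0.39 ± 0.15, SE), but whether the probes overlap was not checked. Chsy1 had only 1 kept probe. An effect of the duplication on its neighbours stays open as well.

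The 6 arrays can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The count of genes past the adjusted threshold was 0 for the real grouping and at most 4 for another, so that all 10 groupings had at least the real count. The count at an unadjusted p was 1074 for the real grouping and at most 1950 for another, with 4 groupings of at least the real count. The count of lists called was 15 and at most 19, with 2 groupings of at least the real count. The highest of these counts came from groupings that put patDp/+ replicate 3 with 2 wild type arrays. For the interval list the median was 0.63 in size for the real grouping and at most 0.36 for another.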
